A study of Homo sapiens with 18 samples.

How the data were processed

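RNA-seq was measured in hPSC, DE, GFP+ sBC and GFP- sBC of the MEL1 line, total ribosome footprints in hPSC and DE, and FLAG-immunoprecipitated footprints in hPSC, DE and GFP+ sBC, with 2 libraries in each of 9 groups. Per the labels, hPSC and DE carry an RPL22-FLAG genotype, and GFP+ sBC for footprints received RPL22-FLAG by lentivirus. RNA libraries were made after RNase H depletion of ribosomal RNA, and footprints after RNase I digestion without cycloheximide. The authors name Salmon, DESeq2, UMI-tools, cutadapt and Bowtie, without versions and without saying which library type each served, and the build GRCh38. The deposited values are expected_counts, that is estimated counts per gene, in 1 table of 57808 genes and 18 libraries, of which 16.8% to 31.3% per library are not whole numbers. They were rounded before every count test. The annotation release is not stated. Of the identifiers 57030 (98.7%) were found in a reference of gene names, some without a symbol, and 19032 rows of the table are protein-coding. Reading frames outside the annotation, peptides and single-read data were not analysed here.

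Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM normalization, robust quasi-likelihood F test, Benjamini-Hochberg, adjusted p under 0.05). Fits held 4 libraries for the GFP sort, for DE against hPSC in RNA and for Ribo. They held 8 RNA libraries for GFP+ sBC against hPSC and DE, 6 libraries for IP-Ribo and 8 footprint libraries for IP-Ribo against Ribo and its difference between stages. The fit of TE held 12 libraries, and the change in TE is the interaction of assay and stage. In all, 14 comparisons were made. Standard errors of log2 fold changes come from these fits. Log2 fold changes of genes with 0 counts in a whole group are given as bounds against a floor of 3 counts over the 2 libraries. Levels are TMM-normalised CPM, with the standard deviation over 2 libraries. Python with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.

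The 22 gene lists were fixed before the data were examined, as were the comparisons, the other settings to be tried and the rule for naming genes. They cover beta cell identity, granules and exocytosis, excitability and incretin response, other islet hormone cells, enterochromaffin-like cells, pancreatic progenitors, exocrine, duct and acinar cells, mesenchyme and matrix, endothelial, immune and neural cells, pluripotency, definitive endoderm, mesoderm and ectoderm, cell cycle, antigen presentation, and type 1 diabetes autoantigens. The rest are ER stress, dissociation stress, cytosolic ribosomal proteins, stress mRNAs with upstream reading frames, mitochondrially encoded mRNAs, noncoding RNAs and replication histones. Of 18 replication histones 17 were found, and the other lists were found in full. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. With an estimated correlation camera uses the residual degrees of freedom of the fit. These were 2 for the GFP sort, for DE against hPSC in RNA and for Ribo, so a list can hardly pass there. A failure to pass in these fits is therefore weak evidence against a shift of the list. A count of members past the threshold is given over all genes and adjusted over the list alone. The rule for naming genes took, per comparison and direction, the 6 largest changes past the threshold with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups. It added up to 4 members past the threshold and 2 not past it from each list with 2 or more members past it, and a fixed set of hormone, lineage and HLA genes. The text names a part of these.

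Alternatives were DESeq2's size factors (RLE), no filter or a stricter filter (1 CPM and 10 counts in 2 libraries), the Wald test of DESeq2 1.42.0, and the replicate number as a block. Others were each library left out in turn, a test against a log2 fold change of 1 (glmTreat), a fit of all 8 RNA libraries, Ribo in place of IP-Ribo, and the removal of mitochondrially encoded genes and listed noncoding RNAs. Chosen after seeing the data were protein-coding genes alone, at least 10 counts in every library of the TE fit, and a block with the replicate numbers of 1 group exchanged. Replicate numbers were not taken as pairs: over all pairs of groups in each fit, the correlation of the replicate difference over genes ran from -0.14 (hPSC and DE IP-Ribo) to 0.12 (DE Ribo and DE IP-Ribo). For GFP+ and GFP- sBC it was 0.1, which does not exclude that equal replicate numbers came from the same sort. Their median log2 ratios of replicate 1 over 2 were 1.21 and 1.54 for dissociation stress genes, but 0.53 and -3.86 for mitochondrially encoded mRNAs. The fit with the replicate number as a block covers that case.

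Depth ran from 6.61 to 92.53 M counts per library. Over genes with at least 20 counts, the Spearman correlation between the 2 libraries of a group lay between 0.922 (GFP+ sBC IP-Ribo) and 0.996 (hPSC RNA and DE RNA). The biological coefficient of variation was 0.37 for the GFP sort, 0.06 for DE against hPSC in RNA, 0.27 for the 8 RNA libraries, 0.34 for IP-Ribo, 0.32 for Ribo, 0.35 for IP-Ribo against Ribo and 0.23 for TE. The tests were tried on simulated data with the measured spread, 100 genes changed 2-fold and 100 changed 4-fold. They recovered 4% and 66% in the GFP sort, 100% and 100% for DE against hPSC in RNA, 13% and 88% for GFP+ sBC against hPSC in RNA. In footprints they recovered 4% and 71% for DE against hPSC in IP-Ribo, 1% and 72% for GFP+ sBC against hPSC in IP-Ribo, and 11% and 87% in Ribo. The figures were 6% and 75% for IP-Ribo against Ribo in hPSC, 8% and 75% for TE against hPSC, and 0% and 0% for the difference of the pull-down between stages. Calls in these trials held more unchanged genes than the nominal 5% in every comparison that made calls, apart from TE of GFP+ sBC (2.4% against hPSC, 1.3% against DE). The share was 30% in Ribo (42 genes), 18.9% for GFP+ sBC against DE in IP-Ribo and 16.7% for DE against hPSC in RNA (40 genes). It was 9.1% in the GFP sort and 5.9% to 12% elsewhere. Each trial was 1 draw that changed 100 genes by each fold, whereas in the measured data 5276 of 15454 genes passed in Ribo. Recovery and this share both depend on how many genes change. Neither therefore carries over to comparisons in which many genes passed.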

Results

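Gene counts were compared among 18 libraries of RNA-seq and ribosome footprint sequencing from MEL1 cells, an established human embryonic stem cell line that carries a GFP reporter in the insulin gene. The cells were taken as pluripotent stem cells (hPSC), as definitive endoderm (DE, the germ layer from which gut and pancreas form) and as stem-cell-derived beta-like cells (sBC) grown in stirred suspension and sorted for GFP. Each of 9 groups held 2 libraries. RNA-seq covered hPSC, DE, GFP+ sBC and GFP- sBC, and total footprints (Ribo) covered hPSC and DE. Footprints pulled down with an antibody against FLAG (IP-Ribo), from ribosomes that carry RPL22-FLAG, covered hPSC, DE and GFP+ sBC. The labels present the series as a search for translated reading frames outside the annotation in beta cells, and its gene-level counts address which annotated genes differed between these cells in RNA and in footprints. The labels do not say that the 2 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries alone, which may be technical.

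The RNA libraries of hPSC held 79.77 and 85.59 M counts, those of DE 92.53 and 91.58 M, those of GFP+ sBC 29.79 and 30.86 M and those of GFP- sBC 37.65 and 27.36 M. The Ribo libraries of hPSC held 22.29 and 26.4 M counts and those of DE 30.17 and 24.26 M. The IP-Ribo libraries of hPSC held 20.57 and 23.11 M counts, those of DE 6.61 and 19.86 M and those of GFP+ sBC 8.73 and 7.59 M. Protein-coding nuclear genes held 54.6% and 62.8% of the counts of the GFP+ sBC IP-Ribo libraries, where 1 feature without a symbol, ENSG00000270103, took 19.8% (Wilson 95% CI 19.7 to 19.8) and 17.2% (17.1 to 17.2). In DE Ribo replicate 1 they held 40.5%, and another such feature, ENSG00000261889, took 25.1% of that library against 4.51% of replicate 2 (Wilson 95% CI 4.5 to 4.52). The protein-coding gene WDR74, named after its values were seen, alone took 10.4% of DE Ribo replicate 1 and 2.3% of replicate 2. In every other library protein-coding genes held between 76.0% and 90.4%. Intervals, and floors for genes at 0, cover counting error only.

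**Figure D1:**
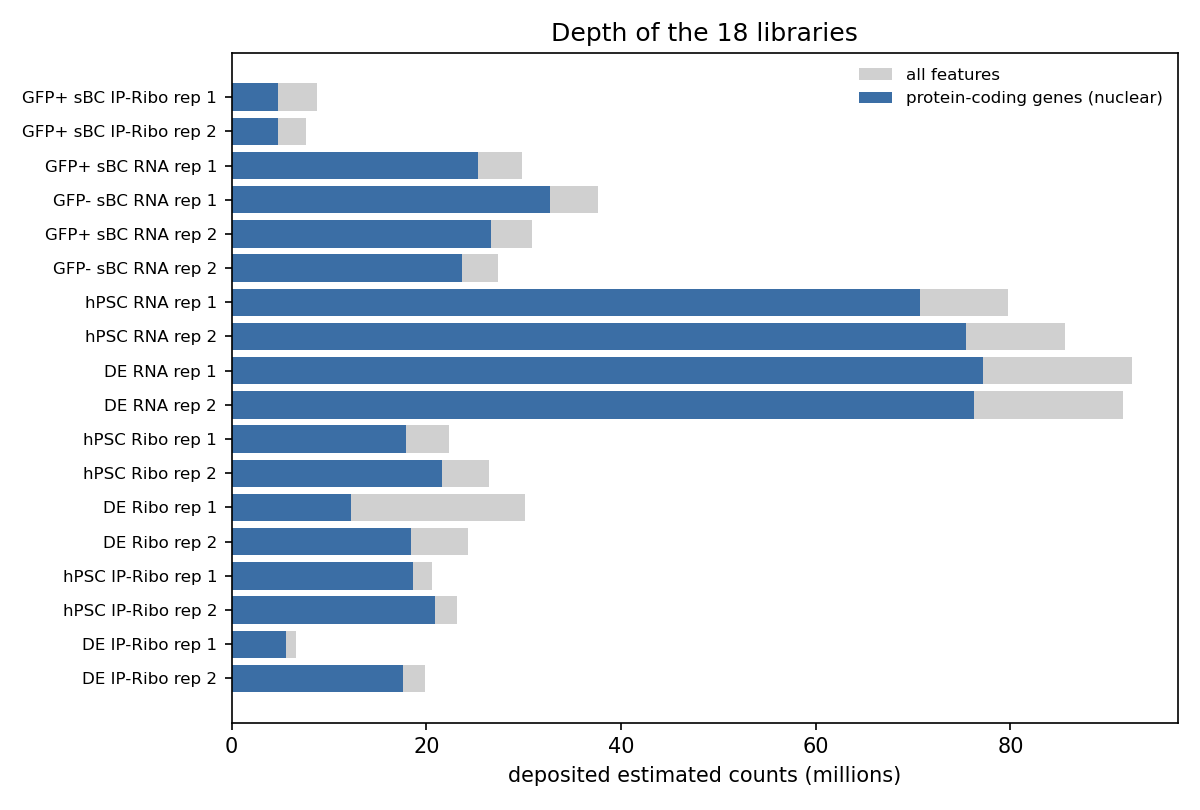
Total counts (grey, in M) and counts in nuclear protein-coding genes (blue, in M) of each of the 18 libraries, 2 per group. The RNA libraries of hPSC and DE hold 79.77 to 92.53 M counts, and DE IP-Ribo replicate 1 holds the fewest, 6.61 M.

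The sort of sBC by GFP asked what sets apart the cells that express insulin. RNA of SST, the hormone of delta cells, was higher in GFP+ cells (log2 fold change 2.77 ± 0.34 SE, adjusted p = 0.0087, 2 libraries per group). RNA of SOX9, a transcription factor of duct and progenitor cells, was lower (-4.35 ± 0.39, adjusted p = 0.0035). The duct chloride channel CFTR was lower by more (-6.16 ± 0.51, adjusted p = 0.00311). INS itself (ENSG00000254647.6, chromosome 11, 2159779 to 2161209, GRCh38) had 4610 ± 304 CPM (counts per 1e6 counts, ± SD) in GFP+ and 1340 ± 510 in GFP- libraries, and its log2 fold change of 1.78 ± 0.41 did not pass the test (adjusted p = 0.0749). Its log2 fold change was 2.20 without GFP- replicate 1 and 1.45 without GFP- replicate 2. Tests in these fits take the spread from the GFP+ libraries alone, which were closer to each other (Spearman correlation 0.984 against 0.932). They therefore do not cover the spread of the GFP- libraries. INS passed without a filter, by DESeq2, with the replicate block and in a fit of all 8 RNA libraries. The most abundant hormone RNA was that of glucagon: GCG had 25500 ± 7500 CPM in GFP+ and 13600 ± 4290 in GFP- libraries (log2 fold change 0.90 ± 0.45, adjusted p = 0.509). It took 3.6% of GFP+ replicate 1 (Wilson 95% CI 3.6 to 3.61) and 2.45% of replicate 2 (2.45 to 2.46).

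Among 24 measured genes of beta cell identity, 1 rose in GFP+ cells, the oxidoreductase ERO1B (2.16 ± 0.39), and 1 fell, the Notch ligand-like gene DLK1 (-4.31 ± 0.41); adjusted over the list alone, 7 rose and 2 fell. ERO1B lost its call without GFP+ replicate 1 (adjusted p = 0.124) and without GFP+ replicate 2 (adjusted p = 0.0644). The zinc transporter of insulin granules SLC30A8 (1.96 ± 0.41, adjusted p = 0.058) and the hormone IAPP (2.81 ± 0.62, adjusted p = 0.0666) did not pass over all genes. SLC30A8 was at 1.51 without GFP- replicate 1 and 2.57 without GFP- replicate 2. IAPP was at 2.54 without GFP- replicate 2 and 3.38 without GFP+ replicate 2. The list's median was 0.5 with adjusted p = 0.307 with an estimated correlation. None of 25 granule and exocytosis genes passed, over all genes or adjusted over the list alone. CHGA, the main protein of secretory granules, had 16500 ± 2510 CPM in GFP+ and 17900 ± 6340 in GFP- libraries (-0.12 ± 0.44). Its sign turned without GFP+ replicate 1 (0.02) and without GFP- replicate 1 (0.27). The beta cell factor NKX6-1 was at -0.53 ± 0.32 (adjusted p = 0.611), and at -0.67 without GFP- replicate 2. SST was the 1 gene past the threshold of 17 genes of other islet hormone cells. None of 12 genes of enterochromaffin-like cells, which are endocrine cells that make serotonin, and none of 13 autoantigens of type 1 diabetes passed, although 4 autoantigen genes rose adjusted over the list alone (list median 0.62, adjusted p = 0.236 with an estimated correlation). Of 16 excitability and incretin genes 1 fell.

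Some genes of other pancreatic cells were lower in GFP+ cells, and none of their lists passed as a group with an estimated correlation. That test had 2 residual degrees of freedom here, so it could hardly pass. By camera at the preset correlation, the progenitor, exocrine and mesenchyme lists were lower (adjusted p = 8.79e-14, 6.9e-22 and 2.04e-12). The estimated correlation of the mesenchyme list, 0.302, lay above that preset. In the pancreatic progenitor list 5 of 16 fell and none rose. Among them were SOX9, the zymogen granule protein GP2 (-5.57 ± 0.50), ONECUT1 (-4.15 ± 0.53) and NR5A2 (-4.12 ± 0.51). Adjusted over the list alone 9 fell (adjusted p = 0.236 with an estimated correlation). Of 16 exocrine, duct and acinar genes 5 fell, among them CFTR, osteopontin SPP1 (-5.37 ± 0.54) and keratin KRT18 (-3.32 ± 0.49). Of the list 13 fell adjusted over the list alone (list median -2.07, adjusted p = 0.191 with an estimated correlation). Of 14 mesenchyme and matrix genes 4 fell, such as SPARC (-4.67 ± 0.54), fibronectin FN1 (-2.25 ± 0.35) and smooth muscle actin ACTA2 (-2.42 ± 0.39), with adjusted p = 0.307 with an estimated correlation. In the cell cycle list 6 of 20 fell, with MKI67 (-4.60 ± 0.77), UBE2C (-4.65 ± 0.77), TOP2A (-4.24 ± 0.59) and CDK1 (-4.04 ± 0.61). Adjusted over the list alone 18 fell (median -2.31, adjusted p = 0.307 with an estimated correlation). Replication histones H3C7 (-5.84 ± 0.97) and H1-5 (-5.12 ± 0.97) were the 2 of 17 that fell. The antigen presentation list had 1 of 25 lower and 9 lower adjusted over the list alone (median -0.64, adjusted p = 0.236 with an estimated correlation); HLA-B (-1.68 ± 0.35, adjusted p = 0.0561) and HLA-C (-1.39 ± 0.39, adjusted p = 0.14) did not pass over all genes. Without GFP- replicate 1 HLA-B was at -1.49 and HLA-C at -0.89, and without GFP- replicate 2 they were at -1.86 and -1.77. Of 10 endothelial, immune and neural markers 3 fell, with a median of 0.06 and a mean of -1.35. Outside the lists, genes that fell included lymphotoxin beta LTB (-7.13 ± 0.54), carbonic anhydrase CA4 (-6.88 ± 0.66), collagen COL11A1 (-6.50 ± 0.69) and nidogen NID2 (-6.29 ± 0.53). Genes that rose included the potassium channel KCNH5 (2.42 ± 0.49), LMO2 (2.40 ± 0.39), the urea transporter SLC14A1 (2.37 ± 0.38), the activin receptor ACVR1C (2.32 ± 0.39) and SPOCK3 (2.29 ± 0.45). Each of these 5 lost its call without GFP+ replicate 1 (adjusted p = 0.269, 0.0894, 0.0655, 0.167 and 0.0631 in that order), and all but ACVR1C lost it without GFP+ replicate 2 as well. Of the genes named as lower, FN1 and ACTA2 lost their call without GFP+ replicate 1 and also without GFP+ replicate 2, and CDK1 lost its call without GFP+ replicate 2.

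In all, 481 of 19797 genes passed in the sort (16 higher and 465 lower in GFP+, edgeR quasi-likelihood test, Benjamini-Hochberg). The GFP- libraries differed from each other: mitochondrially encoded genes took 0.42% of replicate 1 (Wilson 95% CI 0.418 to 0.423) and 4.35% of replicate 2 (4.34 to 4.35), and RPL22, the gene of the FLAG construct, took 0.301% (0.299 to 0.303) and 0.0999% (0.0987 to 0.101). Without GFP- replicate 1 the count was 779 (101 higher) and without GFP- replicate 2 it was 7815 (3587 higher), so it rests on how these 2 libraries differ. Of the 28 named genes past the threshold, 28 kept it without GFP- replicate 1, 28 without GFP- replicate 2, 20 without GFP+ replicate 1 and 20 without GFP+ replicate 2. A fit without a GFP- library takes its spread from the GFP+ libraries, so a call kept there is a weak check. Without a filter on low counts 1596 genes passed, by DESeq2 1265 and with the replicate number as a block 1258. In a fit of all 8 RNA libraries 1263 passed, and 245 passed against a log2 fold change of 1.

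**Figure D2:**
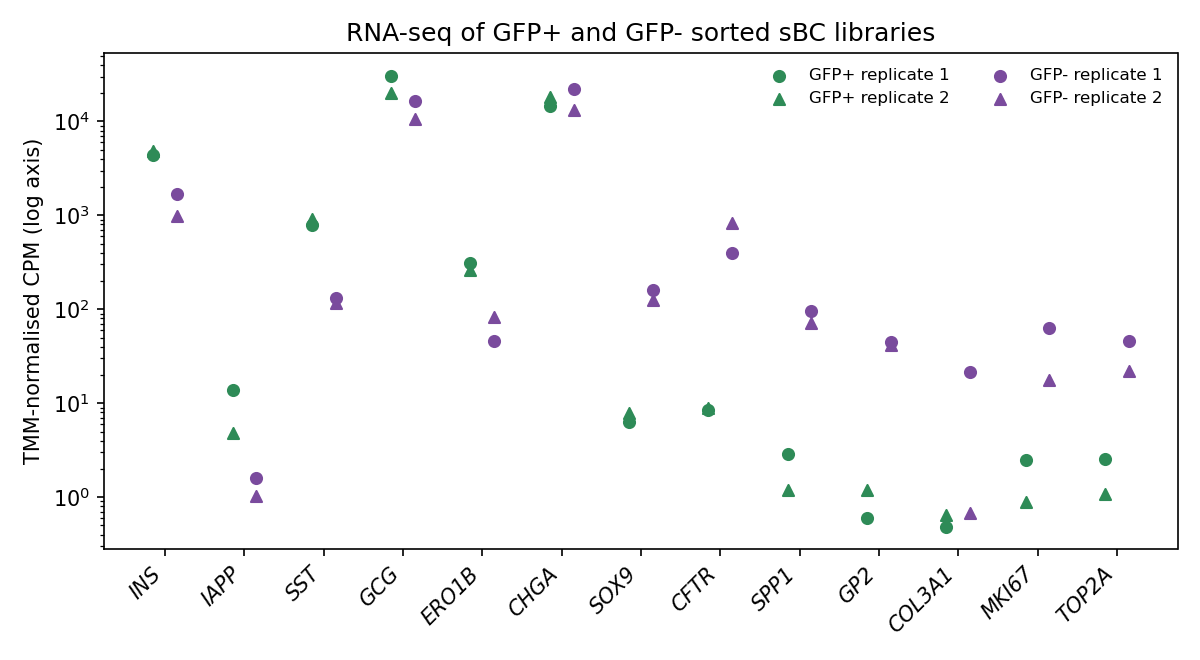
CPM (log axis, TMM-normalised) of 13 genes in RNA-seq of GFP+ (green) and GFP- (purple) sBC, each point 1 library and its shape the replicate. INS lies at 4610 in the mean of GFP+ and 1340 in that of GFP-, CFTR at 8.67 and 614.

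The comparison of DE with hPSC followed the first step of the differentiation in RNA, in total footprints and in FLAG footprints. RNA of the endoderm factors SOX17 (log2 fold change 8.24 ± 0.07 SE, adjusted p = 3.17e-13) and GATA6 (8.69 ± 0.07, adjusted p = 2.53e-13) rose. RNA of the pluripotency factors POU5F1 (-5.42 ± 0.05, adjusted p = 5.04e-13) and NANOG (-5.76 ± 0.06) fell, with 2 libraries per group. SOX17 (ENSG00000164736.5, chromosome 8, 54457935 to 54460892) went from 1.61 ± 0.112 to 470 ± 1.24 CPM (SD), and POU5F1 (ENSG00000204531.17, chromosome 6, 31164337 to 31170682) from 1850 ± 22.9 to 41.6 ± 1.1. In IP-Ribo the same 4 genes changed by 7.04 ± 0.39, 8.05 ± 0.39, -4.64 ± 0.49 and -4.98 ± 0.39 in that order, and in Ribo by 7.74 ± 0.67, 8.04 ± 0.36, -5.08 ± 0.25 and -5.56 ± 0.17, each past the threshold.

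All 23 genes of the definitive endoderm list rose in each of the 3 assays, with medians of 6.7 in RNA, 6.51 in IP-Ribo and 6.38 in Ribo. With an estimated correlation, adjusted p = 0.166 in RNA, adjusted p = 0.0153 in IP-Ribo and adjusted p = 0.27 in Ribo. The RNA and Ribo fits had 2 residual degrees of freedom for that test. In RNA camera at the preset correlation gave adjusted p = 6.89e-109. Beside SOX17 and GATA6, the list held the organiser factor GSC (9.02 ± 0.13 in RNA, 8.01 ± 0.50 in IP-Ribo, 8.56 ± 0.70 in Ribo) and GATA4 (7.85 ± 0.08 in RNA, 7.91 ± 0.42 in IP-Ribo). Others were the secreted antagonist CER1 (8.09 ± 0.09 in RNA) and the chemokine receptor CXCR4 (8.43 ± 0.21 in Ribo). Of 24 pluripotency genes 20 fell in RNA, 17 in IP-Ribo and 18 in Ribo, with medians of -2.25, -2.29 and -2.31, while 4, 2 and 4 rose. With an estimated correlation, adjusted p = 0.386, 0.0798 and 0.197 in that order. SOX2 fell in every assay (-7.90 ± 0.33 in RNA, -6.39 ± 0.61 in IP-Ribo, -6.71 ± 0.76 in Ribo), and RNA of UTF1 (-9.49 ± 0.27), PRDM14 (-6.81 ± 0.11) and, outside the list, FOXD3 (-7.40 ± 0.19) fell too. In IP-Ribo the neuronal kinase-like gene CAMKV fell (-6.42 ± 0.44), and alpha-fetoprotein AFP, with 0 counts in DE, was at least 20.7-fold lower against a floor of 3 counts over the group. In RNA the heart and stress-response gene ANKRD1 rose (9.46 ± 0.55). Mesoderm and ectoderm genes went both ways: 7 of 13 rose and 5 fell in RNA (median 0.51, mean -0.52), and 2 of 6 fell in IP-Ribo. So did pancreatic progenitor genes, of which 6 of 13 rose and 6 fell in RNA (median -0.05, mean 1.49). Over all genes 7992 of 20634 rose and 7599 fell in RNA, so such splits are not particular to these lists.

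Many ribosomal protein genes were lower in DE: 65 of 78 fell in RNA, 43 in IP-Ribo and 50 in Ribo, with medians of -0.27, -1.06 and -0.89, and adjusted p = 0.756, 0.488 and 0.197 with an estimated correlation. Examples were RPL23 (-0.82 ± 0.05) and RPSA (-0.76 ± 0.04) in RNA, and RPS12 (-2.03 ± 0.26) and RPL34 (-1.89 ± 0.35) in IP-Ribo. Cell cycle genes fell in 16 of 20 cases in RNA, 9 in IP-Ribo and 16 in Ribo, with adjusted p = 0.57, 0.548 and 0.408 with an estimated correlation. The replication helicase genes MCM5 (-1.31 ± 0.04) and MCM2 (-1.24 ± 0.05 in RNA, -1.90 ± 0.19 in Ribo) and the clamp PCNA (-1.12 ± 0.05) were among them. In footprints MCM3 (-1.37 ± 0.20) and CCNB1 (-1.60 ± 0.28) fell in IP-Ribo and CENPF (-1.91 ± 0.16) in Ribo. Replication histone H1-3 fell in RNA (-1.36 ± 0.06), 1 of 12 of 17 histone genes that did; 5 fell in Ribo and none of 17 in IP-Ribo. Genes of endoplasmic reticulum (ER) stress rose, 16 of 18 in RNA, 6 in IP-Ribo and 9 in Ribo, with adjusted p = 0.57, 0.496 and 0.27 with an estimated correlation. The transcription factor ATF3 rose in RNA (2.07 ± 0.10), IP-Ribo (1.89 ± 0.30) and Ribo (2.44 ± 0.19), and DDIT3 in RNA (2.23 ± 0.12). Of 14 dissociation stress genes 10 rose and 2 fell in RNA (adjusted p = 0.386 with an estimated correlation). In IP-Ribo 5 of 13 rose, EGR1 among them (4.10 ± 0.58), and in Ribo 5 of 14. In the list of stress mRNAs with upstream reading frames 8 of 15 rose in RNA, such as PPP1R15A (1.67 ± 0.07), and 3 fell, such as EPRS1 (-1.45 ± 0.05) and AMD1 (-1.37 ± 0.05), the enzyme that leads into polyamine synthesis. EPRS1 and AMD1 fell also in IP-Ribo (-2.40 ± 0.24 and -2.78 ± 0.40) and in Ribo (-2.24 ± 0.17 and -1.91 ± 0.37).

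Antigen presentation genes went both ways at this step: 13 of 26 rose and 12 fell in RNA (list median 0.01, mean -0.12). Over all genes 7992 of 20634 rose and 7599 fell in RNA, so this split is not particular to the list. HLA-B (2.26 ± 0.06) and HLA-C (1.75 ± 0.08) rose, and the immunoproteasome subunits PSMB8 (-2.55 ± 0.17) and PSMB9 (-2.49 ± 0.35) fell. In IP-Ribo PSMB8 fell (-2.19 ± 0.35) and HLA-B was at 0.70 ± 0.21 (adjusted p = 0.0523); in Ribo PSMB8 fell (-1.96 ± 0.28) and HLA-B rose (1.22 ± 0.30). Of 22 granule genes measured in RNA, which hPSC also express, 15 fell and 6 rose. In IP-Ribo 12 of 25 fell, with adjusted p = 0.386 in RNA and 0.496 in IP-Ribo with an estimated correlation. Among those that fell were CHGA (-3.06 ± 0.14 in RNA, -3.15 ± 0.31 in IP-Ribo, -3.07 ± 0.36 in Ribo) and CHGB (-3.66 ± 0.26 in RNA). Beta cell identity genes, like genes at large, went both ways in RNA (7 of 17 higher, 8 lower), with the beta cell factor MAFA lower (-3.91 ± 0.19). Of 14 mesenchyme and matrix genes 9 rose and 4 fell in RNA (adjusted p = 0.539 with an estimated correlation). FN1 was among those that rose (4.14 ± 0.12 in RNA, 3.27 ± 0.29 in IP-Ribo, 4.17 ± 0.23 in Ribo). RPL22 itself fell in Ribo (-0.76 ± 0.22, adjusted p = 0.0456), a borderline call lost in 3 of 4 fits with 1 library left out (adjusted p from 0.0868 to 0.268).

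In RNA 15591 of 20634 genes passed between DE and hPSC (7992 higher, 7599 lower), in IP-Ribo 3573 of 16018 (1566 higher, 2007 lower) and in Ribo 5276 of 15454 (2661 higher, 2615 lower), by the edgeR quasi-likelihood test. The split in IP-Ribo depends on the setting. With RLE size factors 1645 were higher and 1856 lower. With protein-coding genes alone, chosen after seeing the data, 2159 were higher and 2097 lower, but this changes the genes tested as well as the scale. Across genes, which are not independent replicates, the log2 changes in RNA had Pearson r = 0.8 and Spearman rho = 0.8 with those in IP-Ribo over 14437 genes. In both, 3329 genes passed, 99.2% of them with the same sign. Between RNA and Ribo r was 0.82 and rho 0.83 over 14140 genes, and between IP-Ribo and Ribo r was 0.8 and rho 0.82 over 14148 genes. The RNA count fell to 6561 in a fit of all 8 RNA libraries, where the sBC libraries add to the spread. Of the 31 named RNA genes past the threshold 26 kept their call there. The Ribo count fell to 201 without hPSC replicate 1 and 73 without hPSC replicate 2; 8 and 6 of the 17 genes named from it then kept their call. The IP-Ribo count fell to 1097 without hPSC replicate 1, 1317 without hPSC replicate 2 and 1888 without DE replicate 1, and 17, 19 and 18 of its 19 named genes past the threshold kept theirs. Against a log2 fold change of 1, 5334 genes passed in RNA, 1055 in IP-Ribo and 1487 in Ribo.

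**Figure D3:**
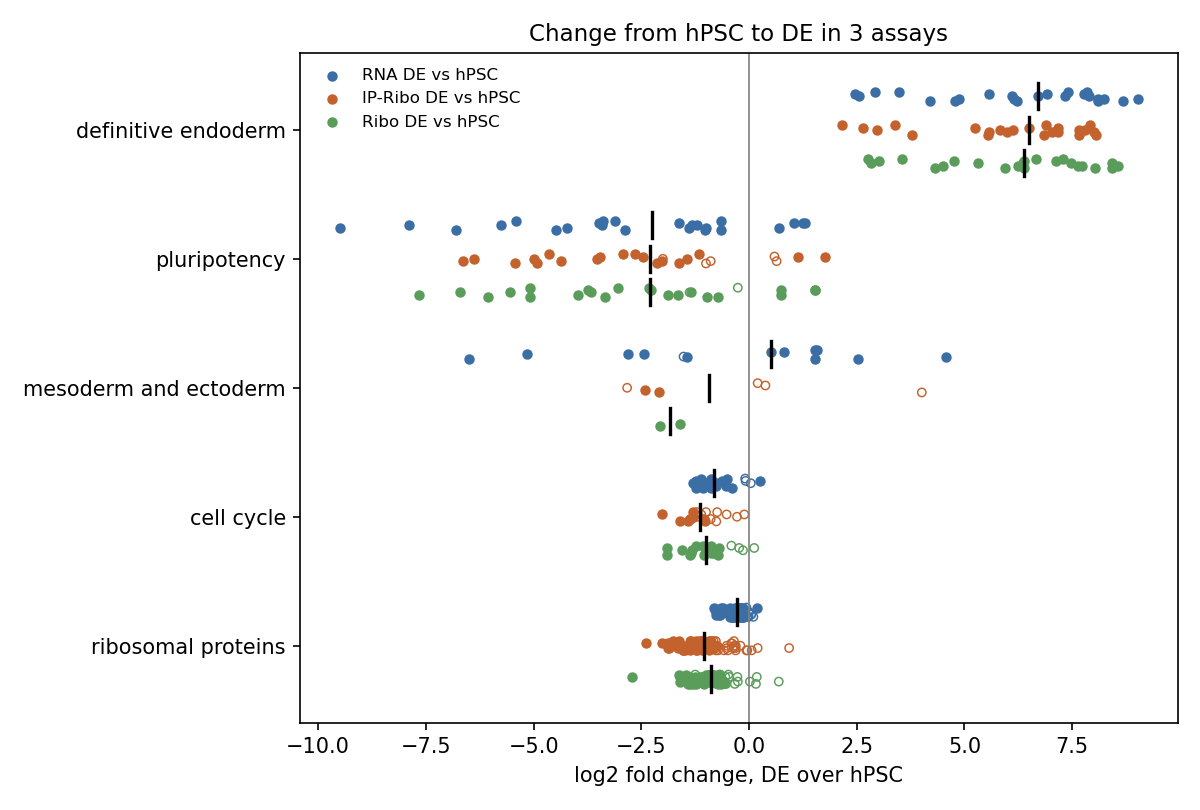
Log2 fold change of DE over hPSC (x axis) for the members of 5 fixed gene lists in RNA (blue), IP-Ribo (orange) and Ribo (green); filled points passed the test, open points did not, and black bars are list medians. Definitive endoderm genes have medians of 6.7, 6.51 and 6.38.

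GFP+ sBC were compared with hPSC and DE to ask which RNAs and footprints the beta-like cells had gained. GCG and INS had 0 counts in the RNA and IP-Ribo libraries of hPSC and DE; RNA of GCG was at least 1180000-fold and RNA of INS at least 214000-fold higher in GFP+ sBC than in hPSC, against a floor of 3 counts over the 2 libraries of a group. Footprints of GCG were at least 524000-fold and those of INS at least 42500-fold higher. Against DE the bounds were 1300000-fold and 235000-fold in RNA and 466000-fold and 37700-fold in footprints. CHGA rose in RNA (log2 fold change 10.58 ± 0.39 SE against hPSC, 13.69 ± 0.43 against DE) and in footprints (11.88 ± 0.38 and 15.03 ± 0.42), with 2 libraries per group. The cells had lost POU5F1 RNA (-9.83 ± 0.26 against hPSC, adjusted p = 5.5e-06). In these comparisons sBC also differ from hPSC and DE in genotype label and library set, which cannot be told apart from the stage.

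Of 24 beta cell identity genes 21 rose in RNA against hPSC and 2 fell (median 7.66, and 7.31 with genes at 0 in a group set to their bound). RFX6 was at least 14600-fold, PDX1 at least 4240-fold and the glucose-6-phosphatase-like G6PC2 at least 3800-fold higher. NKX6-1 rose by 9.64 ± 0.30, the amyloid hormone IAPP rose by 2.57 ± 0.51, and MAFA fell (-2.91 ± 0.66). The size of the IAPP change leans on GFP+ replicate 1, with 13.7 CPM against 4.8 in replicate 2 and a mean of 1.55 in hPSC. The call held with an estimated correlation (adjusted p = 0.0128), as it did in footprints against hPSC (20 of 22 higher, median 8.34, with bounds 7.93, adjusted p = 0.0461). In footprints against DE, where 19 of 22 rose, it did not (adjusted p = 0.111). Granule and exocytosis genes rose in 22 of 25 cases in RNA against hPSC, 25 of 25 in RNA against DE, 22 of 25 in footprints against hPSC and 24 of 25 in footprints against DE. With an estimated correlation, adjusted p = 0.0198, 0.0154, 0.0461 and 0.1 in that order. Among them were the convertase PCSK2 (10.82 ± 0.40) and the granin SCG2 (10.89 ± 0.86) in RNA against hPSC. All but 1 of 16 excitability genes rose in RNA against hPSC, such as the sulfonylurea receptor ABCC8 (10.46 ± 0.36, 11.61 ± 0.39 against DE) and the channel KCNH6 (7.99 ± 0.28), and KCNMA1 rose against DE (9.61 ± 0.37). Genes of other islet hormone cells rose in 16 of 17 cases against hPSC, with SST at 12.45 ± 0.53. All 12 enterochromaffin-like genes rose against hPSC in RNA and in footprints (adjusted p = 0.107 and 0.0461 with an estimated correlation), such as DDC (10.54 ± 0.49 in RNA, 11.59 ± 0.54 in footprints) and TPH1 (9.80 ± 0.91), the enzyme that starts serotonin synthesis. Autoantigens of type 1 diabetes rose in 11 of 14 cases in RNA against hPSC (median 5.05, with bounds 5.7), TSPAN7 among them (7.46 ± 0.45), as did PTPRN in footprints (8.71 ± 0.53) and GAD2 in RNA against DE (9.87 ± 0.35).

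Most antigen presentation genes were higher in GFP+ sBC. Against hPSC 18 of 26 rose in RNA and 3 fell (median 1.73, adjusted p = 0.0914 with an estimated correlation), and 19 of 24 rose in footprints (median 3.44, adjusted p = 0.0461 with an estimated correlation). HLA-B (ENSG00000234745.10, chromosome 6, 31353875 to 31357179) went from 10.7 ± 0.147 to 111 ± 28.2 CPM (SD) in RNA (3.38 ± 0.25) and from 11.7 ± 0.69 to 699 ± 47.8 in footprints (5.90 ± 0.25). The HLA class I partner B2M rose by 4.56 ± 0.46 in RNA and 5.58 ± 0.48 in footprints, and HLA-C by 2.50 ± 0.31 in RNA. The invariant chain CD74 rose by 4.53 ± 0.28 and 6.56 ± 0.54, the trimming peptidase ERAP1 by 6.92 ± 0.44 in footprints and HLA-E by 6.25 ± 0.36 in footprints. Against DE 18 of 26 rose in RNA (adjusted p = 0.0705 with an estimated correlation) and 20 of 24 in footprints (adjusted p = 0.0739 with an estimated correlation). In RNA and in footprints HLA-B rose by 1.17 ± 0.23 and 5.20 ± 0.25, and B2M by 4.24 ± 0.45 and 6.25 ± 0.50. ERAP1 rose by 3.78 ± 0.24 and 7.51 ± 0.46, and CD74 by 5.29 ± 0.29 and 7.02 ± 0.57. GFP- libraries had 356 ± 71.4 CPM (SD) of HLA-B RNA. ER stress genes rose in 12 of 18 cases in RNA and 13 of 18 in footprints against hPSC (adjusted p = 0.0793 and 0.115 with an estimated correlation). Among them were the chaperone HSPA5 (2.48 ± 0.19 in RNA), DNAJC3 (2.66 ± 0.35 in RNA), SEL1L (3.13 ± 0.34 in RNA, 5.20 ± 0.29 in footprints), DNAJB9 (5.26 ± 0.33) and HYOU1 (3.66 ± 0.24). Footprints of the chaperone HSP90B1 (3.91 ± 0.36) and of SEL1L (4.95 ± 0.29) rose against DE. Of the stress mRNAs with upstream reading frames ATF4 (-1.99 ± 0.27 in RNA, -2.85 ± 0.21 in footprints), ATF5 (-2.19 ± 0.27) and CEBPB (-2.49 ± 0.29) fell against DE.

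Pluripotency genes fell in 23 of 24 cases in RNA against hPSC (median -8.07, with bounds -7.57, adjusted p = 0.0198 with an estimated correlation) and in 21 of 24 in footprints. Examples were NANOG (-8.24 ± 0.51 in RNA, at least 484-fold lower in footprints), TDGF1 (-11.42 ± 0.38) and SOX2 (-5.10 ± 0.58 in footprints). The microRNA host gene MIR302CHG was at least 5720-fold lower in RNA. Of 23 definitive endoderm genes 21 fell in RNA against DE: SOX17 was at least 11300-fold, EOMES at least 11000-fold and GSC at least 4640-fold lower, and GATA6 fell (-4.75 ± 0.21 in RNA, -4.50 ± 0.32 in footprints). POU5F1 fell further from DE (-4.35 ± 0.21). All 20 cell cycle genes fell in RNA and in footprints against hPSC and against DE. Among them were CDK1 (-8.71 ± 0.40 in RNA against hPSC, -8.70 ± 0.40 against DE, -5.18 ± 0.43 in footprints against DE), RRM2 (-8.11 ± 0.41), CCNA2 (-6.40 ± 0.51 in footprints) and BUB1 (-6.03 ± 0.45 in footprints). With an estimated correlation, adjusted p = 0.159 in RNA and 0.115 in footprints against hPSC. All 17 replication histones fell with them, H2BC9 by the most of those named (-7.36 ± 0.40 in RNA, -6.93 ± 0.29 in footprints; adjusted p = 0.2 and 0.159 with an estimated correlation). All 78 ribosomal protein genes fell in RNA against hPSC and against DE (medians -2.51 and -2.14), and 77 and 69 of them fell in footprints (medians -2.68 and -1.76). Examples were RPL35 (-3.47 ± 0.19 against hPSC, -3.06 ± 0.19 against DE) and RPS21 (-3.44 ± 0.34) in RNA. In footprints RPL32 (-4.70 ± 0.26) and RPL30 (-4.25 ± 0.38) fell against hPSC and RPL29 (-4.13 ± 0.44) and RPS25 (-3.89 ± 0.36) against DE. For these genes adjusted p = 0.0914 and 0.11 in RNA and 0.115 and 0.209 in footprints with an estimated correlation. The polyamine enzymes ODC1 (-3.44 ± 0.22 in RNA) and AMD1 (-5.13 ± 0.47 in footprints) fell against hPSC.

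Markers of other cell types went more than 1 way. Of 17 exocrine, duct and acinar genes 11 rose and 4 fell in RNA against hPSC (median 2.29, with bounds 1.99, adjusted p = 0.126 with an estimated correlation). In footprints 13 of 16 rose and 1 fell (median 6.27, with bounds 4.8, adjusted p = 0.0461 with an estimated correlation). Of 16 mesenchyme and matrix genes 2 rose and 6 fell in RNA against hPSC, such as PDGFRA (-4.04 ± 0.34). Against DE 4 rose and 10 fell, such as SPARC (-5.82 ± 0.45) and TAGLN (-7.36 ± 0.75, -6.47 ± 0.40 in footprints). In footprints FN1 (7.27 ± 0.34 against hPSC, 3.99 ± 0.29 against DE) and ACTA2 (3.85 ± 0.41 against hPSC) rose. So did the duct and stem cell marker PROM1 (6.53 ± 0.39 against DE), the adhesion gene CDH1 (8.09 ± 0.28 against DE) and SPP1 (8.37 ± 0.61 against DE). The liver-type secreted proteins SERPINA1 and AGT were at least 46000-fold and 13200-fold higher in footprints against hPSC. Pancreatic progenitor genes rose in 9 of 16 cases and fell in 5 in RNA against hPSC, with FOXA1 at 5.95 ± 0.25. GATA6 footprints rose against hPSC (3.55 ± 0.34), and RPL22 footprints rose against DE (1.38 ± 0.34, adjusted p = 0.0123), but not without GFP+ sBC IP-Ribo replicate 1 (0.81, adjusted p = 0.0864) or DE IP-Ribo replicate 1 (1.10, adjusted p = 0.0778). Mitochondrially encoded mRNAs rose in 5 of 13 cases in RNA and 8 of 11 in footprints against hPSC, with adjusted p = 0.726 and 0.429 with an estimated correlation.

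In RNA 14302 of 23321 genes passed against hPSC (7088 higher, 7214 lower) and 14163 against DE (6967 higher, 7196 lower); in IP-Ribo 9437 of 16018 passed against hPSC (4865 higher, 4572 lower) and 8418 against DE (4451 higher, 3967 lower). Against a log2 fold change of 1 the counts were 9333, 8852, 6517 and 5552. Across genes, which are not independent replicates, the change from hPSC to GFP+ sBC in RNA had Pearson r = 0.83 and Spearman rho = 0.83 with that in IP-Ribo over 14798 genes. Of 7524 genes past the threshold in both, 97.5% had the same sign.

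The comparison of IP-Ribo with Ribo within a stage asked what the FLAG pull-down changes in the footprints. Footprints of mitochondrially encoded mRNAs, which mitochondrial ribosomes without RPL22 translate, were lower after the pull-down in hPSC. This held for the cytochrome oxidase subunit MT-CO3 (log2 fold change -4.39 ± 0.58 SE, adjusted p = 0.0213) and the ATP synthase subunit MT-ATP6 (-4.37 ± 0.61, adjusted p = 0.0256), with 2 libraries per group. In DE MT-CO3 (-4.09 ± 0.58, adjusted p = 0.0276), MT-CO1 (-3.71 ± 0.29) and MT-CO2 (-3.43 ± 0.40) were lower. Of 13 such genes 9 fell in hPSC and 5 in DE, and all 13 fell adjusted over the list alone in each stage. The medians were -3.39 and -2.82, with adjusted p = 0.102 and 0.116 with an estimated correlation. Of 18 noncoding RNAs 3 fell in each stage, and 9 and 12 adjusted over the list alone (medians -1.27 and -2.32, adjusted p = 0.216 and 0.116 with an estimated correlation). Those past the threshold over all genes were the nuclear RNA MALAT1 (-2.39 ± 0.36 in hPSC, -4.69 ± 0.40 in DE) and the snoRNA host genes GAS5 (-2.75 ± 0.31 and -2.57 ± 0.31) and ZFAS1 (-2.38 ± 0.34 and -2.35 ± 0.34). The mitochondrial tRNA MT-TN (-4.76 ± 0.56 and -6.78 ± 0.56) and the Y RNA RNY4 (-5.26 ± 0.65 and -7.44 ± 0.73) were lower in both stages, and the microRNA MIR182 in DE (-6.82 ± 0.53). No gene passed in either direction among 78 ribosomal protein genes, of which 2 fell in hPSC and none in DE adjusted over the list alone, and RPL22 was at -0.57 ± 0.24 in hPSC and -0.29 ± 0.23 in DE. Few genes rose, with the somatostatin receptor SSTR3 (1.72 ± 0.30) in hPSC and FAM72A (1.17 ± 0.18) in DE among them.

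Of 16679 genes 192 passed in hPSC (15 higher, 177 lower in IP-Ribo) and 144 in DE (10 higher, 134 lower), and 85 passed in both with the same sign. The counts rest on both libraries of each group. Leaving out 1 gave 57 or 37 in hPSC (without Ribo replicate 1 or 2) and 34 or 18 (without IP-Ribo replicate 1 or 2). In DE it gave 83 or 332 (without Ribo replicate 1 or 2) and 36 or 172 (without IP-Ribo replicate 1 or 2). Of the named genes past the threshold, between 0 and 3 of 8 kept their call in hPSC and between 3 and 9 of 10 in DE. The difference between the stages in the effect of the pull-down passed for 2 genes, both pseudogenes, named after their values were seen: EZRP1 (-7.16 ± 0.55, adjusted p = 0.0249) and WDR82P2 (adjusted p = 0.0278), whose count was 0 in both DE Ribo libraries. With 1 library left out between 0 and 11 genes passed. WDR82P2 lost its call in all 8 of these fits (adjusted p from 0.052 to 0.139) and EZRP1 in 5 of 8. DESeq2 called 62 genes there. In edgeR 663 of 16679 genes had an unadjusted p under 0.05, fewer than the 5% that chance alone gives. The test recovered 0% of 100 simulated 4-fold differences, so few differences of this kind could be seen.

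**Figure D4:**
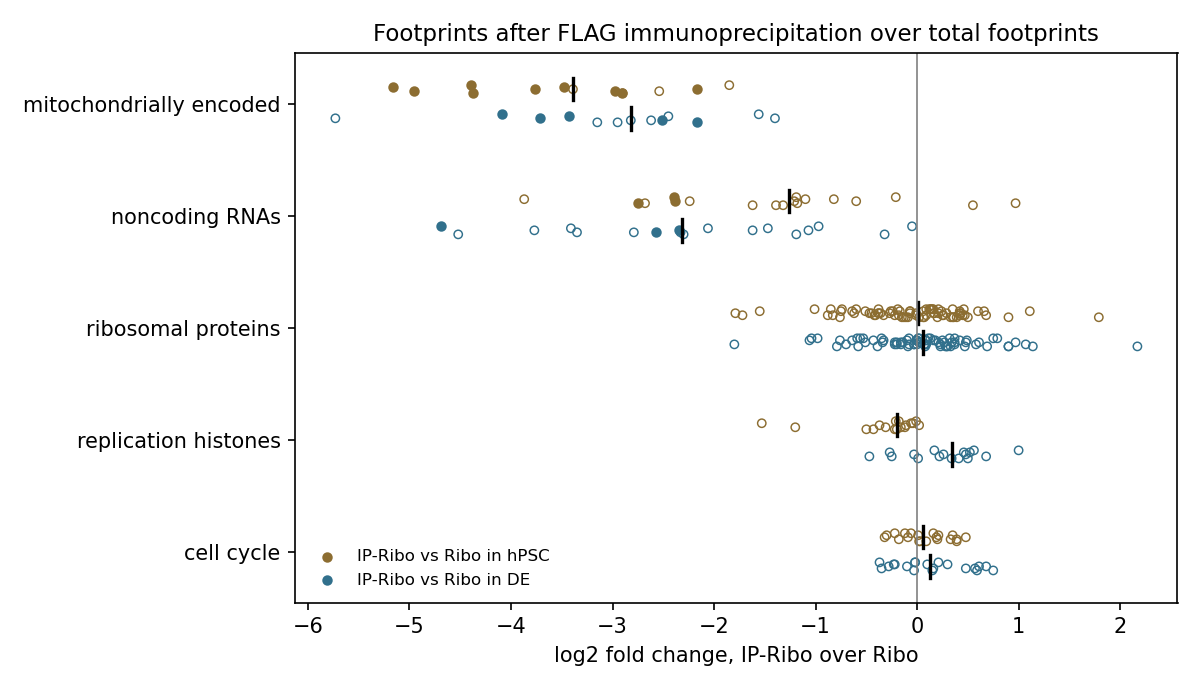
Log2 fold change of IP-Ribo over Ribo (x axis) for the members of 5 fixed gene lists in hPSC (brown) and DE (blue); filled points passed the test, open points did not, and black bars are list medians. Mitochondrially encoded mRNAs have medians of -3.39 and -2.82, ribosomal protein genes 0.01 and 0.05.

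Translational efficiency (TE), the ratio of IP-Ribo to RNA counts, was compared between stages in 1 model over 12 libraries to ask where footprints changed by more or less than RNA. Between GFP+ sBC and hPSC, TE of HLA-B rose (log2 change 2.27 ± 0.25 SE, adjusted p = 0.000351), as did that of HLA-F (4.70 ± 0.48, adjusted p = 0.000228) and of FN1 (3.71 ± 0.32, adjusted p = 0.000107). TE of the immediate early gene FOS fell (-5.74 ± 0.98, adjusted p = 0.00539), with 2 libraries per group and assay. Against DE HLA-B (3.49 ± 0.26), HLA-F (4.14 ± 0.49), FN1 (4.22 ± 0.31) and FOS (-5.90 ± 1.05) changed in the same directions. In GFP+ sBC the TE fit gave HLA-F a mean of 1.04 CPM in RNA and 420 in IP-Ribo, SPP1 1.54 and 121, and FN1 256 and 1940 (n = 2 each). The counts are estimates, and how reads were assigned among HLA genes alike in sequence was not tested. TE of single HLA genes may therefore reflect that assignment.

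Of 26 antigen presentation genes 11 had higher TE in GFP+ sBC than in hPSC, and 16 adjusted over the list alone (adjusted p = 0.0265 with an estimated correlation). Beside HLA-B and HLA-F these included the loading factor TAPBP (2.80 ± 0.33), the immunoproteasome subunit PSMB10 (3.38 ± 0.61) and the class II chain HLA-DRB1 (3.04 ± 0.40). Against DE 12 of 26 were higher (adjusted p = 0.0134 with an estimated correlation), with B2M (1.45 ± 0.43) and HLA-C (1.38 ± 0.41) near the threshold (adjusted p = 0.0478 and 0.0497), a call that each lost in 6 of 8 fits with 1 library left out. Of 17 exocrine, duct and acinar genes 7 were higher against hPSC and 9 against DE (adjusted p = 0.0265 and 0.0565 with an estimated correlation), such as SPP1 (4.75 ± 0.58 against hPSC), and among the progenitor genes SOX9 (4.08 ± 0.57). Of 14 mesenchyme and matrix genes 7 and 5 were higher (adjusted p = 0.045 and 0.0442 with an estimated correlation), such as PDGFRA (4.89 ± 0.74 against hPSC) and SPARC (4.34 ± 0.45 against DE). Of 12 endothelial, immune and neural markers 5 and 4 were higher (adjusted p = 0.045 and 0.0442 with an estimated correlation). Too few of these markers had at least 10 counts in every library for a summary, so genes of low count weigh in that call. Among genes with at least 10 counts in every library of a comparison, 11 of 20 antigen presentation genes, 3 of 7 exocrine genes and 5 of 8 mesenchyme genes were higher against hPSC, with medians of 1.43, 1.37 and 2.58. Against DE 10 of 18, 2 of 6 and 3 of 7 were higher in that order, with medians of 1.55, 1.3 and 1.32.

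Of 20 cell cycle genes 8 had higher TE against hPSC and 7 against DE, such as TOP2A (3.44 ± 0.70 and 3.51 ± 0.70), CDK1 (2.97 ± 0.53 against DE) and MKI67 (2.64 ± 0.71 against hPSC), with adjusted p = 0.515 and 0.387 with an estimated correlation. MKI67 lost its call in 6 of 8 fits with 1 library left out and was at 1.35 (adjusted p = 0.25) without GFP+ sBC IP-Ribo replicate 1. ER stress genes were higher in 4 of 18 cases against hPSC and lower in 1, and higher in 5 and lower in 2 against DE (adjusted p = 0.395 and 0.374 with an estimated correlation). The chaperones DNAJB9 (3.05 ± 0.29 and 2.26 ± 0.29) and HYOU1 (2.04 ± 0.22 and 1.95 ± 0.22), SEL1L (1.83 ± 0.25 against hPSC) and HSP90B1 (1.59 ± 0.35 against DE) were higher and ATF4 (-1.40 ± 0.20 against DE) was lower. The granins CHGA (1.06 ± 0.26) and CHGB (1.37 ± 0.37) were among 5 of 25 granule genes that were higher against hPSC (adjusted p = 0.515 with an estimated correlation). These calls were weak: with 1 library left out CHGA lost its call in 7 of 8 fits (down to 0.69 without GFP+ sBC IP-Ribo replicate 2) and CHGB in 6 of 8 (down to 0.70 without hPSC IP-Ribo replicate 2). Dissociation stress genes had lower TE in 4 of 14 cases against hPSC and 5 against DE, with JUNB (-2.09 ± 0.60 and -2.84 ± 0.59) and IER2 (-1.95 ± 0.55 against hPSC) beside FOS (adjusted p = 0.248 and 0.131 with an estimated correlation). The GFP+ RNA libraries differed on this list by a median log2 ratio of 1.21 (replicate 1 over 2). Against hPSC JUNB was at -1.33 (adjusted p = 0.146) and IER2 at -1.22 (adjusted p = 0.104) without GFP+ RNA replicate 1, and they lost their call in 6 and 5 of 8 fits. Ribosomal protein genes were lower in 21 of 78 cases and higher in 3 against hPSC, and lower in 6 and higher in 5 against DE. Among the lower were RPL32 (-2.14 ± 0.25 against hPSC), RPL30 (-1.92 ± 0.37 against hPSC), RPL29 (-2.27 ± 0.44 against DE) and RPS25 (-1.90 ± 0.35 against DE). Against hPSC adjusted p = 0.515 with an estimated correlation. In the list of stress mRNAs with upstream reading frames 4 of 15 were higher and 2 lower against hPSC, with the polyamine enzymes moving apart (ODC1 1.44 ± 0.30, AMD1 -2.38 ± 0.42), and IFRD1 was lower against DE (-1.99 ± 0.34).

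Mitochondrially encoded mRNAs were lower in 7 of 13 cases against DE, such as MT-CYB (-2.87 ± 0.49) and MT-ND2 (-2.82 ± 0.52), with adjusted p = 0.2 with an estimated correlation. Noncoding RNAs went both ways: the snoRNA hosts GAS5 (4.21 ± 0.50 against hPSC, 3.89 ± 0.50 against DE) and SNHG1 (4.03 ± 0.57 against hPSC) were higher, and NEAT1 (-3.20 ± 0.59 against hPSC) and SNHG14 (-3.16 ± 0.58 against DE) were lower. The GFP+ sBC pull-downs stood apart in their share of RNA other than nuclear mRNA. Mitochondrially encoded genes took 4.08% and 3.99% of these libraries against 0.196% to 0.321% of the other IP-Ribo libraries, and the spliceosomal RNA RNU11 took 8.83% and 7.46% against 0.535% to 1.31%. In RNA the mitochondrial share was higher in GFP+ sBC too (5.34% and 4.15% against 0.486% to 0.876% in hPSC and DE). Without Ribo libraries of sBC, a weaker pull-down cannot be told apart from a change in TE for RNAs that it lowered in hPSC and DE, GAS5 among them. The histone H2AC6 was lower against hPSC (-1.93 ± 0.24). Between DE and hPSC few genes differed in TE. CLN8 (3.25 ± 0.34), which acts in transport out of the ER, and the antisense RNAs CCDC90B-AS1 (2.50 ± 0.28) and UGDH-AS1 (2.35 ± 0.35) were higher in DE. RGPD3 (-2.98 ± 0.41), the readthrough gene RPL17-C18orf32 (-2.16 ± 0.30) and SNORA53 (-2.35 ± 0.33) were lower. For SNORA53, the antisense RNAs and the noncoding RNAs above, TE is a ratio of counts that alone does not show translation. ATF4 (1.08 ± 0.20, adjusted p = 0.0905) and HLA-B (-1.22 ± 0.25, adjusted p = 0.126) did not pass. Without DE IP-Ribo replicate 2 HLA-B was at -1.45. No ribosomal protein gene of 78 passed between DE and hPSC, over all genes or adjusted over the list alone (median -0.43, adjusted p = 0.696 with an estimated correlation). No mitochondrially encoded mRNA of 13 passed over all genes (median 1.11, adjusted p = 0.696 with an estimated correlation).

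TE differed for 3327 of 22210 genes between GFP+ sBC and hPSC (2443 higher, 884 lower) and for 3144 between GFP+ sBC and DE (1963 higher, 1181 lower), by the edgeR quasi-likelihood test. With DESeq2's size factors (RLE) the median over all genes moved from 0.07 to -0.06 against hPSC and from -0.09 to 0.01 against DE, and the split became 2179 higher and 1305 lower against hPSC and 2172 and 952 against DE. With protein-coding genes alone, chosen after seeing the data, the split was 2708 higher and 801 lower against hPSC and 2813 and 653 against DE, with medians of 0.19 and 0.25. Without hPSC RNA replicate 1 or 2 the count against hPSC was 1748 or 1749, and without GFP+ sBC RNA replicate 1 or 2 it was 2165 or 2174. Without DE RNA replicate 1 or 2 the count against DE was 1519 or 1443, and without GFP+ sBC RNA replicate 1 or 2 it was 1939 or 1934. Of the 27 and 21 named genes past the threshold, between 21 and 25 and between 18 and 21 kept their call.

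Between DE and hPSC 37 genes passed (22 higher, 15 lower), and with RLE size factors 34 (15 higher, 19 lower), as the median over all genes moved from 0.16 to -0.06. DESeq2 called 643. Without DE IP-Ribo replicate 2, which leaves the library of 6.61 M counts alone in its group, 1730 genes passed; without hPSC RNA replicate 1 or 2, DE RNA replicate 1 or 2, or hPSC IP-Ribo replicate 1, the count was 5, 9, 2, 1 or 18. Of the 6 genes named as past the threshold between 0 and 6 kept their call with 1 library left out. With Ribo in place of IP-Ribo 68 genes passed, of which 7 were among the 37, and 1 of the 6 named genes kept its call.

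**Figure D5:**
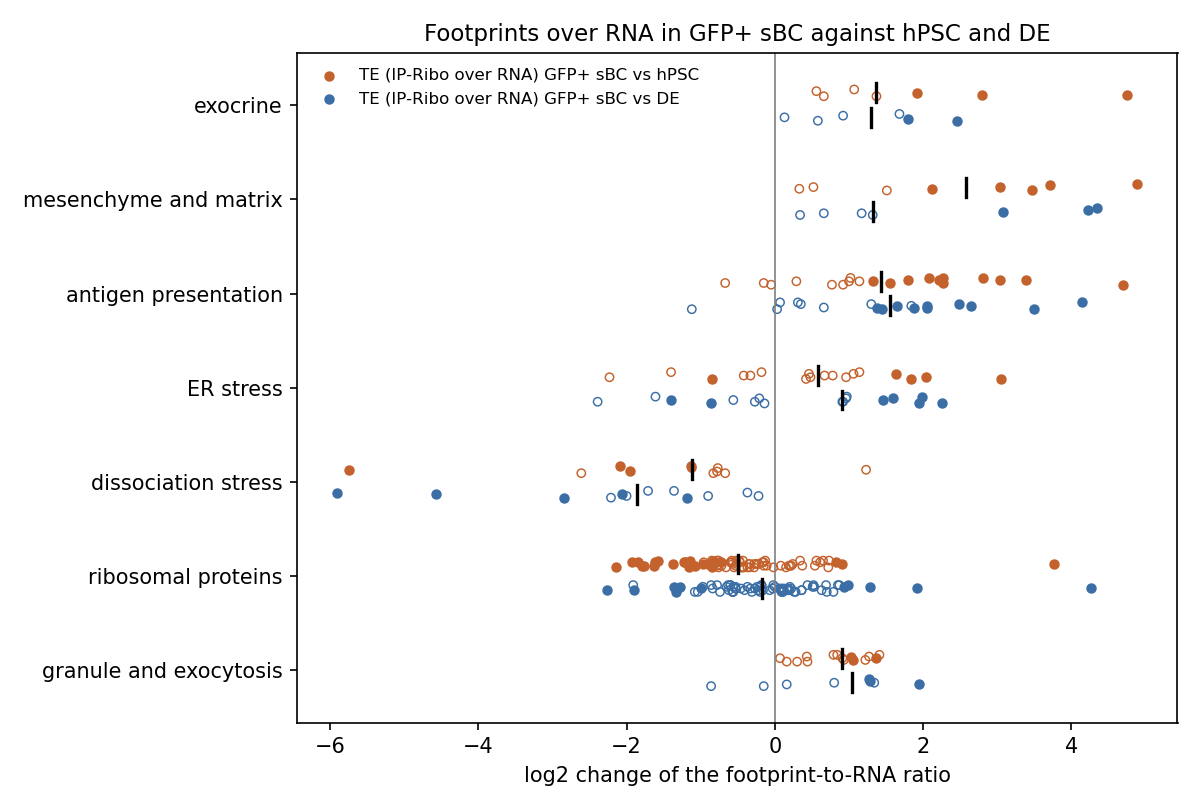
Change in TE (log2 of IP-Ribo over RNA, x axis) of GFP+ sBC against hPSC (orange) and DE (blue) for members of 7 fixed gene lists with at least 10 counts in every library, with filled points past the test and black bars at list medians. Antigen presentation genes have medians of 1.43 and 1.55, dissociation stress genes -1.12 and -1.85.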

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

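Of the tests below, that of other cells was chosen only after levels of listed genes in these libraries were seen, and that of structured RNA before its result was seen. The 4 comparisons that test an interaction with stage were listed here whatever their outcome. For the pull-down in DE and hPSC 2 genes passed, and 0 of these kept their call with the replicate block. TE differed for 37 genes between DE and hPSC, for 3327 between GFP+ sBC and hPSC and for 3144 between GFP+ sBC and DE.

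In GFP+ sBC, some duct, matrix and HLA genes had more footprints than their RNA would give in hPSC or DE: 7 of 17 exocrine, 7 of 14 matrix and 11 of 26 antigen presentation genes had higher TE against hPSC, and 9, 5 and 12 against DE, where the exocrine list did not pass with an estimated correlation (adjusted p = 0.0565). Structured and unannotated RNA in the footprint libraries is argued against as the source of a shifted scale, since with protein-coding genes alone the median TE change of the exocrine list against hPSC was 3.51, and 3.47 with all genes, though genes of low count carry much of its size (1.07 among those with at least 10 counts in every library). Whether cells other than those of the GFP+ RNA libraries, such as GFP- cells, were in the GFP+ sBC footprint libraries is not decided, although the cells were sorted for GFP. The difference of footprints and RNA in GFP+ sBC correlated across 14860 genes with that of GFP- and GFP+ RNA at r = 0.27 or more when no library was shared. Both differences subtract GFP+ RNA, whose 2 libraries had a Spearman correlation of 0.984, so a positive r can arise without such cells. The differences in hPSC and DE, at -0.02 and 0.02, do not subtract GFP+ RNA, so they are no control for this. A change in translation in beta-like cells, the lentivirus and the separate preparation of these cells stay open as untested.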

How the results depend on the processing

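Of 268 gene results 187 kept their direction and side of the threshold in every alternative run for them. With the cause not tested unless named, results stayed the same in 266 of 268 cases with RLE size factors, 260 of 268 by DESeq2 and 256 of 268 with the replicate block. They stayed in 259 of 268 without a filter and 1114 of 1304 with 1 library left out, where a lone library is taken to vary like the other groups. CHGA reversed in the GFP sort (0.02 without GFP+ replicate 1, 0.27 without GFP- replicate 1, range -0.43 to 0.27). In the order GFP sort, DE against hPSC in RNA, GFP+ sBC against hPSC and DE in RNA, DE against hPSC, then GFP+ sBC against DE in IP-Ribo, Ribo, IP-Ribo against Ribo in hPSC and DE, and TE of DE against hPSC and GFP+ sBC against hPSC and DE, glmTreat, which asks for a larger change, gave 245, 5334, 9333, 8852, 1055, 5552, 1487, 61, 78, 12, 1350 and 1020 genes.

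DESeq2 gave 1265 in the GFP sort, 633 and 905 for IP-Ribo against Ribo in hPSC and DE, 62 for the difference between these and 643 for TE of DE against hPSC; no filter gave 1596, 958, 1526, 214 and 69. The replicate block gave 1258 in the GFP sort, 0 for the difference of the pull-down (577 at unadjusted p under 0.05) and 22 for TE of DE against hPSC. Protein-coding genes alone, fewer genes by construction and chosen after seeing the data, gave 82, 52, 0 (497 at unadjusted p under 0.05) and 17 for the last 4 of these. For TE of DE against hPSC, Ribo in place of IP-Ribo gave 68 and at least 10 counts in every library, also chosen after seeing the data, 16. All 8 RNA libraries gave 1263 in the GFP sort and 6561 for DE against hPSC.

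With 1 library left out, counts ran from 384 to 7815 in the GFP sort, 13960 to 14182 for DE against hPSC in RNA, 10052 to 11391 and 9609 to 11021 for GFP+ sBC in RNA against hPSC and DE. They ran from 1097 to 3144, 6801 to 7949 and 6757 to 7316 in IP-Ribo, 73 to 5782 in Ribo, 18 to 57 and 36 to 332 for IP-Ribo against Ribo. The ranges were 0 to 11 for its difference, and 1 to 1730, 1748 to 3275 and 1443 to 3592 for TE. With an estimated correlation 0 lists passed in the GFP sort, in RNA and Ribo of DE against hPSC, in IP-Ribo of GFP+ sBC against DE, in the 3 comparisons of the pull-down and in TE of DE against hPSC. Elsewhere 6 and 7 (RNA of GFP+ sBC against hPSC and DE), 1 and 7 (IP-Ribo of DE and of GFP+ sBC against hPSC) and 4 and 3 (TE of GFP+ sBC against hPSC and DE) passed. At the preset correlation of 0.01, 16 lists passed in the GFP sort, and 10 in RNA and 8 in Ribo of DE against hPSC. The count was 2 in each comparison of the pull-down and in TE of DE against hPSC, and 9 in each TE comparison of GFP+ sBC. The exocrine list in the GFP sort had adjusted p = 6.9e-22 by camera at the preset. Its estimated correlation was -0.009 (adjusted p = 0.191), so a high correlation does not explain that loss. The test with an estimated correlation rests on the residual degrees of freedom of the fit, 2 here, and the preset test does not. A planned test of IP-Ribo against RNA within GFP+ sBC was conditional and not run. Depth limits DE IP-Ribo replicate 1 (6.61 M counts) and the GFP+ sBC IP-Ribo libraries most.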

Other observations

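Between GFP+ and GFP- sBC none of 18 ER stress genes (median 0.13), 14 dissociation stress genes (-0.52), 15 stress mRNAs with upstream reading frames (-0.05, mean -0.16), 78 ribosomal protein genes (-0.58, adjusted p = 0.423 with an estimated correlation) or 13 mitochondrially encoded mRNAs (1.08, adjusted p = 0.423 with an estimated correlation) passed the edgeR test, over all genes or adjusted over the list alone. Of 23 noncoding RNAs 1 fell (median 0.14, mean -0.11), of 20 pluripotency genes 1, of 18 definitive endoderm genes 3 and of 13 mesoderm and ectoderm genes 1. Between GFP+ sBC and hPSC 9 of 14 dissociation stress genes rose in RNA and 2 fell, and 6 of 13 rose in footprints and 3 fell. Of 15 stress mRNAs with upstream reading frames 7 fell in RNA against hPSC and 7 against DE, and 4 and 2 rose. Noncoding RNAs fell in 13 of 23 cases against hPSC in RNA and rose in 6 (median -0.83, mean 0.41).

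Tests of the RPL22-FLAG construct and of another mix of cells in the GFP- sorts, and both tests of hormone and granule RNAs below, were chosen only after the result was seen, and that of mitochondrially encoded transcripts before. GFP- replicate 1 stood apart from replicate 2. A lower yield of mitochondrially encoded transcripts alone is argued against: without these genes 25.4% of 14165 protein-coding genes were over 2-fold apart between the GFP- libraries and 2.8% between the GFP+ libraries, a ratio of 9.14. Sequence from the RPL22-FLAG construct in that library stays open: RPL22 had rank 1 of 79 ribosomal protein genes by the ratio of replicate 1 over 2, but this restates its larger share there and decides nothing. Another mix of cells may add to it, as the median log2 ratio of granule genes lay -1.38 from that of mesenchyme genes (-0.21 against 1.16), and this stays open too.

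GFP- libraries held hormone and granule RNAs. GFP+ cells carried over with the mean INS level of that sort are argued against as the whole source. INS reached 0.37 and 0.21 of its GFP+ mean in GFP- replicates 1 and 2. The lower quartile of 25 granule genes was at 0.47 and 0.66, a smallest excess of 0.1. As the sort selects on the INS reporter, carried-over cells low in INS would give the same pattern, so their carry-over stays open. Endocrine cells with little INS may be in the GFP- sort, and this stays open too. The medians of the granule list (0.62 and 0.73) and of the 12 enterochromaffin-like genes (0.58 and 1.17) exceeded the INS fraction by 0.22 or more. Yet hPSC also express granule genes, so these do not mark endocrine cells alone. Single genes spread widely: CHGA was at 1.36 and 0.81, NKX6-1 at 1.6 and 1.27, GCG at 0.65 and 0.41, TPH1 at 0.25 and 1.32, SST at 0.16 and 0.14 and G6PC2 at 0.11 and 0.14. Silencing of the reporter or late activation of INS in part of the cells was not tested.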
